A study of Macaca mulatta with 2 samples.

How the data were processed

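RNA was taken with TRIzol from biopsies of 2 rhesus macaque placentas delivered by cesarean section, and polyadenylated RNA was sequenced as stranded paired reads of 50 bp on an Illumina HiSeq, per the labels' protocols. The labels put both samples in 1 group, so the group and the numbers 1 and 2 of the placentas come from the labels, and no contrast between groups was made.

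FPKM values were deposited by the authors, 1 value for each of 37839 human RefSeq transcripts in each placenta. They were made with TopHat and Cufflinks on the human build hg19, per the submitters' processing notes. Versions and settings, including how multi-mapping reads and strand were treated, are not given in the sources used here. Macaque reads were thus placed on human sequence, so a gene that has diverged between the species can read low, and members of multi-copy families (growth hormone and placental lactogen, PSG, CGB, galectin, globin, HLA and kallikrein genes) can take each other's reads. The coverage column, the mean depth per base of each transcript, per the file headers, was used only for a check on its ratio to FPKM and in the search for whole reads. Transcript lengths in bases, per the file headers, were used to match random lists in that check. The start positions count from 0, since for 3640 transcripts the end minus the start equals the length while none does counting from 1, and 1 was added before printing.

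The design written before the data were examined kept rows of one symbol apart as the main setting and summed them as an alternative. The files turned out to hold 1 row per transcript, so FPKM was summed per gene symbol and the rows kept apart became the alternative. Estimates carried the status OK for 37725 transcripts in placenta 1 and 37731 in placenta 2, low data for 94 in each, failed for 15 and 9, and too much data for 5 in each. Of 25240 gene symbols, 95 with any status other than OK in either placenta were left out, which leaves 25145. The usable genes include 1318 small RNA genes, and 18369 of all gene symbols have 1 transcript. A symbol placed on both X and Y occurred in 20 cases.

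Depth was looked for in the low values. For genes with 1 transcript between 0.01 and 1 FPKM, coverage times transcript length divided by the read length of 50 bp came within 0.05 of a whole number for 11.8% of 3787 transcripts in placenta 1 and 13.0% of 3812 in placenta 2, where chance gives 10%, so whole reads could not be recovered and no count test was run. The depth behind each value is unknown, no interval of counting error can be given, and an FPKM of 0 is reported only as listed at 0.

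Detection was counted at 1 FPKM. Levels and differences used log2(FPKM + 1), a scale that understates the differences of low genes. Means and SDs over the placentas are of FPKM. Genes differing at least 2-fold were counted among those with a mean of 5 FPKM or more. The agreement of the placentas was measured over genes, with no p-value. Gene lists for placental cell types, functions and outgroup tissues, 33 in all, were fixed before the data were examined. Of 692 gene names written in them, 689 matched the files, covering 671 different genes, and 6 entries had a status other than OK. Of the matches, 4 used older human symbols found in the files (HERV-FRD for ERVFRD-1, HERV-V1 for ERVV-1, HERV-V2 for ERVV-2 and L3MBTL for L3MBTL1), and ERVW-1 was matched through its older symbol ERVWE1. ERVH48-1, TRBC1 and RBFOX3 were not analysed here. The level of a list is the percentile of its median among 10000 random lists of the same size from all usable genes. Its difference is the percentile of its median difference, over members at a mean of 1 FPKM or more, among 10000 random lists matched on mean expression in 20 bins. Lists in the upper or lower 2.5% of random lists are described as standing apart. These percentiles describe these libraries and are no test over animals.

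Genes named in the text follow a rule fixed before the data were examined. It takes the 25 genes with the highest mean, the 3 highest members of each list, members under 1 FPKM in both placentas, a set of placental hormone, steroid, fusion and growth genes whatever their value, and the 12 highest and 12 lowest differences among genes with a mean of 5 FPKM or more. Genes whose symbols begin as those of microRNA precursors, small nucleolar, spliceosomal and related RNAs were left out of the rankings as small RNA genes. The rule also excluded mitochondrially encoded genes, but no separate step removed any. Genes named outside this rule are said to have been chosen after their values were seen.

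The percentile procedures were tested on simulated data. Of 100 lists of 20 genes with no shift drawn from 12890 genes, 3 lay in the upper 2.5% of random lists and 3 in the lower 2.5% in the test of differences, and all 100 lay in the upper 2.5% after shifts of 0.5, 1 or 2 on the log2 scale. In the test of level over 25145 genes, 3 of 100 random lists and 100 of 100 lists of highly expressed genes lay there. Simulated members were drawn independently of each other, whereas members of a real list can vary together. These rates therefore do not carry over to the real lists. Alternatives changed the FPKM floor, the pseudocount (0.1, 0.01 and 5), the filters on mean FPKM, the scaling of the placentas, the small RNA genes, multi-copy families and the placentas used. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9. The reference table of macaque genes that came with the data names another assembly and was not used.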

Results

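Polyadenylated RNA from villous placenta, the branched fetal tissue that exchanges nutrients and hormones with maternal blood, was sequenced from 2 rhesus macaques. The labels place both placentas at 80% of gestation, at 128 and 131 days, without saying which placenta had which age. Both samples form 1 group, named here placenta 1 and placenta 2, and no treatment or control was compared. The description therefore covers which genes the macaque placenta expressed and how far the placentas lay apart. Values are FPKM (fragments scaled to transcript length and to the number of mapped fragments) for human RefSeq transcripts in the human build hg19, summed per gene. The labels state about 15000000 read pairs of 50 bp for each library. The files hold no read counts, so the depth behind a single value is unknown, and n = 2 placentas is the only replication. With n = 2, an SD describes these placentas and supports no p-value.

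Of 25145 genes with usable estimates, 12176 (48.4%) reached 1 FPKM in both placentas. Placenta 1 had 12742 genes at that level and placenta 2 had 12771. Another 566 genes reached it in placenta 1 alone and 595 in placenta 2 alone. At the other end, 391 genes reached 100 FPKM in both placentas and 24 reached 1000 FPKM, small RNA genes left out. Genes of very short RNAs (microRNA precursors, small nucleolar, spliceosomal and related RNAs) held 55.3% of summed FPKM in placenta 1 and 51.9% in placenta 2. Because FPKM divides by a very short length for these genes, they were left out of the rankings by abundance.

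Among the most abundant genes, with small RNA genes left out, were those of placental hormones and secreted proteins. CSHL1, a growth hormone family member (chromosome 17, 61986965 to 61988618), had the highest mean among genes with usable estimates, 12221 ± 3180.0 FPKM (SD, n = 2). Genes with a status of too much data, such as the family member GH1, could not be ranked. WFDC2, a secreted protein of the whey acidic protein family (chromosome 20, 44098394 to 44110172), followed at 11088 ± 1580 FPKM (SD, n = 2), and the maternally expressed noncoding RNA H19 (chromosome 11, 2016406 to 2019065) at 10402 ± 2879 FPKM (SD, n = 2). SERPINE2, a serine protease inhibitor (chromosome 2, 224839765 to 224904036), reached 9625 ± 451 FPKM (SD, n = 2). The fifth gene, IGFBP1, a binding protein of insulin-like growth factors (chromosome 7, 45927959 to 45933267), averaged 6513 FPKM, but its SD of 9112 exceeded the mean because placenta 1 had 69.2 and placenta 2 had 12956 FPKM. GH2, placental growth hormone, stood at 5132 ± 894 FPKM, the matrix protein FBLN1 at 3530 ± 963, the actin-binding TMSB10 at 2870 ± 428, the fetal growth factor IGF2 at 2764 ± 592 and the placental lactogen gene CSH1 at 2758 ± 1303 (SD, n = 2 each). The rest of the 25 most abundant genes were INSL4, SAT1, NOTUM, IL13RA2, TFPI2, GDF15, CDKN1C, PRG2, TPT1, S100A6, PSG5, B2M, NEAT1, RPS18 and TXN, from 2674 ± 272 FPKM for INSL4 down to 1078 ± 93.6 for TXN. Ranked within each placenta, which need not give the genes just named, the top 10 genes held 19.4% of summed FPKM in placenta 1 and 19.1% in placenta 2. The top 100 of each held 39.2% and 38.5%. With small RNA genes ranked too, the top 100 share was 57.7% on average, and only 6 of the 25 genes stayed in the top 25.

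Syncytiotrophoblast, the fused hormone-secreting surface of the villi, was strongly represented. Of 32 marker genes, 28 reached 1 FPKM in both placentas, and the list median was 209 FPKM in placenta 1 and 216 in placenta 2. This median lay at the 100th percentile of 10000 random lists of the same size, meaning above every one of them. Besides the genes above, the list included CGA, the alpha subunit shared by the glycoprotein hormones, at 92.0 ± 29.8 FPKM, KISS1, the precursor of kisspeptin, at 50.6 ± 13.2, and PSG1, a pregnancy-specific glycoprotein, at 158 ± 99.3 (SD, n = 2 each). The genes of the chorionic gonadotropin beta subunit were near or at 0. CGB had 0.136 FPKM in placenta 1 and was listed at 0 in placenta 2, CGB5 was listed at 0 in both, and CGB8 had 0.0643 and 0.259 FPKM. The leptin gene LEP had 0.192 ± 0.0483 FPKM (SD, n = 2). Summed over the growth hormone and placental lactogen family, expression was 20961 ± 5471 FPKM (SD, n = 2), which was 7.06% of summed FPKM without small RNA genes in placenta 1 and 4.67% in placenta 2. All 11 PSG genes reached 1 FPKM in both placentas, with a sum of 5933 ± 819 FPKM (SD, n = 2). How this expression divides among members is uncertain, since macaque reads were assigned to near-identical human copies. GH1 had a status of too much data and was listed at 0, so the growth hormone family sum and shares hold nothing for it and may be too low.

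The other trophoblast lists also stood at the 100th percentile. For villous cytotrophoblast, the progenitor layer beneath the syncytium, 22 of 24 markers reached 1 FPKM in both placentas, with medians of 41.8 and 40.5 FPKM in placentas 1 and 2. Its most abundant members were PAGE4 at 315 ± 32.4 FPKM and the epithelial keratins KRT18 at 279 ± 14.4 and KRT8 at 209 ± 1.34 (SD, n = 2 each). TP63 and ELF5, transcription factors of trophoblast progenitors, were under 1 FPKM in both. For extravillous trophoblast, the invasive lineage, 17 of 20 markers reached the floor, with medians of 107 and 124 FPKM. SERPINE2 led this list, followed by the Wnt-inactivating enzyme NOTUM at 2185 ± 433 FPKM and PRG2 at 1719 ± 584 (SD, n = 2 each). HLA-G had 93.3 ± 17.1 FPKM, whereas PAPPA2, a protease of insulin-like growth factor binding proteins, had only 0.292 ± 0.0320 (SD, n = 2 each). Macaque reads assigned to human HLA-G can come from other class I genes, so that value is uncertain.

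Genes of trophoblast fusion were expressed, with all 15 listed members at 1 FPKM or more in both placentas. The list medians were 21.4 and 18.04 FPKM, at the 99.98th percentile. GCM1, the transcription factor that drives syncytium formation (chromosome 6, 52991759 to 53013624), had 131 ± 3.91 FPKM, the membrane-binding protein ANXA5 had 163 ± 9.17 and the gap junction protein GJA1 had 90.1 ± 15.3 (SD, n = 2 each). Among envelope genes of endogenous retroviruses, ERVFRD-1 (syncytin-2, chromosome 6, 11102722 to 11112071) had 45.9 ± 11.1 FPKM and ERVV-2 had 37.9 ± 4.18. ERVV-1 had 12.4 ± 1.38, while ERVW-1 (syncytin-1, chromosome 7, 92097694 to 92107229) had 1.62 ± 0.319 (SD, n = 2 each). ERVV-2 was named after its values were seen. These values rest on reads that matched the human copies of the retroviral sequences.

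Steroid synthesis genes ranged from abundant to nearly undetected. Of 29 listed genes, 16 reached 1 FPKM in both placentas and 12 stayed under it in both. The medians were 3.56 and 2.65 FPKM, at the 92.0th percentile, or the 99.7th among genes at a mean of 1 FPKM or more. CYP11A1, which starts steroid synthesis by cleaving the cholesterol side chain (chromosome 15, 74630103 to 74660081), had 75.4 ± 0.505 FPKM, and LDLR, the receptor that takes up cholesterol, had 122 ± 3.83 (SD, n = 2 each). HSD17B2, which oxidises estradiol and testosterone, had 47.8 ± 6.76 FPKM, and HSD3B1, which forms progesterone, had 3.11 ± 0.643 (SD, n = 2 each). CYP17A1, needed for androgen synthesis, had 0.177 ± 0.0148 FPKM and STAR, the cholesterol carrier of other steroid-forming organs, 0.694 ± 0.238 (SD, n = 2 each). Aromatase, CYP19A1 (chromosome 15, 51500254 to 51630795), summed to 27.8 and 34.4 FPKM, but one of its transcripts carried a low-data status, so it was kept out of the list.

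Corticotropin-releasing hormone, a placental peptide hormone of anthropoid primates, was among the abundant transcripts, and its binding protein was not. CRH (chromosome 8, 67088612 to 67090846) had 251 ± 179 FPKM (SD, n = 2), made of 377 FPKM in placenta 1 and 124 in placenta 2. CRHBP had 0.0452 ± 0.0330 FPKM (SD, n = 2). Of the 18 genes listed for this hormone and glucocorticoid metabolism, 9 reached 1 FPKM in both placentas, with medians of 2.16 and 4.22 FPKM at the 78.3rd percentile, or the 99.5th among genes at a mean of 1 FPKM or more. HSD11B2, which inactivates cortisol, had 155 ± 63.1 FPKM, and HSD11B1, which regenerates it, had 79.8 ± 26.7 (SD, n = 2 each). HSD11B1 was named after its values were seen. The receptor genes CRHR1, CRHR2 and MC2R were under 1 FPKM in both placentas.

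Angiogenic factors reached 1 FPKM in both placentas for 19 of 22 genes, with medians of 12.5 and 15.7 FPKM at the 100th percentile. The hypoxia-inducible transcription factor EPAS1 had 415 ± 45.5 FPKM, INHA, the inhibin alpha subunit, 317 ± 29.7, and SERPINE1, an inhibitor of plasminogen activation, 201 ± 139 (SD, n = 2 each). FLT1, a receptor of vascular endothelial growth factor (chromosome 13, 28874483 to 29069265), had 81.4 ± 5.18 FPKM and its placental ligand PGF had 12.2 ± 1.96 (SD, n = 2 each). Among only the genes at a mean of 1 FPKM or more, the level of this list stood at the 95.8th percentile.

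Nutrient transport genes were almost all expressed, 33 of 35 at 1 FPKM or more in both placentas, with medians of 22.1 and 21.1 FPKM at the 100th percentile. The glucose transporter SLC2A1 had 342 ± 46.7 FPKM, the fatty acid transporter CD36 had 116 ± 0.160 and the lactate transporter SLC16A3 had 109 ± 27.8 (SD, n = 2 each).

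Imprinted genes, expressed from 1 parental copy in other mammals studied, included several of the most abundant transcripts. Of 20 paternally expressed genes, 16 reached 1 FPKM in both placentas, with medians of 10.1 and 10.9 FPKM at the 99.98th percentile. IGF2 led them, followed by MEST at 298 ± 38.6 FPKM and DLK1 at 139 ± 38.0 (SD, n = 2 each). This level stood at the 97.2nd percentile among genes at a mean of 1 FPKM or more and at the 84.2nd when genes with several transcripts were left out. Of 17 maternally expressed genes, 11 reached the floor, with medians of 6.72 and 5.16 FPKM at the 97.47th percentile, just short of the upper 2.5% of random lists, or at the 98.6th in placenta 1 alone and the 95.7th in placenta 2 alone. H19, TFPI2 at 1883 ± 439.7 FPKM and CDKN1C, a brake on cell division, at 1744 ± 376 led this list (SD, n = 2 each). Allele-specific expression was not measured.

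Cells of the villous core were also represented. All 20 fibroblast and extracellular matrix genes reached 1 FPKM in both placentas, with medians of 67.8 and 78.6 FPKM at the 100th percentile. FBLN1 led them, followed by SPARC at 416 ± 39.5 FPKM and the collagen gene COL3A1 at 199 ± 27.2 (SD, n = 2 each). Endothelial genes reached the floor in 18 of 20 cases, with medians of 7.02 and 7.24 FPKM at the 99.4th percentile, and included PECAM1 at 139 ± 47.4, ENG at 119 ± 11.02 and ESAM at 79.4 ± 12.6 (SD, n = 2 each). Pericyte and smooth muscle genes reached it in 13 of 14 cases, with medians of 8.74 and 8.09 FPKM at the 98.5th percentile, led by TAGLN at 140 ± 2.97, ACTA2 at 58.3 ± 10.9 and MYL9 at 41.0 ± 2.11 (SD, n = 2 each). Among genes at a mean of 1 FPKM or more, the last 2 lists stood at the 63.7th and 60.7th percentiles. Macrophage genes, which include markers of Hofbauer cells, the fetal macrophages of the villi, reached 1 FPKM in 19 of 20 cases, with medians of 13.95 and 19.4 FPKM at the 100th percentile. They were led by the complement genes C1QB at 71.0 ± 17.8 and C1QC at 60.9 ± 11.3 and by SPP1 at 47.7 ± 41.9 (SD, n = 2 each).

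Lists of blood, decidual, amniotic and unrelated tissues did not stand in the upper 2.5% of random lists in level. Lymphocyte and natural killer genes reached 1 FPKM in both placentas in 4 of 20 cases, with medians of 0.166 and 2.80 FPKM at the 54.7th percentile, or the 39.5th with a pseudocount of 0.1 and the 2.48th among genes at a mean of 1 FPKM or more. This list differed between the placentas, at the 5.98th percentile in placenta 1 alone and the 85.5th in placenta 2 alone. Neutrophil genes did so in 6 of 13 cases, with medians of 0.613 and 0.997 FPKM at the 39.9th percentile, led by CSF3R at 66.2 ± 17.2 and CAMP at 27.5 ± 10.7 (SD, n = 2 each). Erythroid genes did so in 9 of 21 cases, with medians of 0.577 and 0.757 FPKM at the 30.9th percentile, or the 97.4th among genes at a mean of 1 FPKM or more and the 56.7th over genes with 1 transcript. The adult beta globin gene HBB nevertheless had 511 ± 131 FPKM and HBD had 97.6 ± 33.6 (SD, n = 2 each), and reads of the globin copies cannot be assigned with certainty. Decidua, the maternal lining of the pregnant uterus, had 7 of 17 genes at the floor in both placentas, with medians of 0.160 and 5.85 FPKM at the 72.3rd percentile, made of the 7.53rd in placenta 1 alone and the 97.37th in placenta 2 alone, or the 47.0th with a pseudocount of 0.1 and the 28.8th among genes at a mean of 1 FPKM or more. Amnion and squamous epithelium had 5 of 14, with medians of 0.887 and 0.682 FPKM at the 33.9th percentile, or the 92.6th among genes at a mean of 1 FPKM or more, led by S100A14 at 26.8 ± 1.59, SFN at 20.8 ± 6.10 and ITGB4 at 19.9 ± 0.158 (SD, n = 2 each). Of 75 genes from 4 outgroup tissues, 8 reached 1 FPKM in both placentas, 2 from each tissue. The liver list stood at the 1.13th percentile with medians of 0.0646 and 0.0463 FPKM, and skeletal muscle and heart at the 0.87th with 0.0552 and 0.0694. Neurons stood at the 1.92nd with 0.0544 and 0.109, and pancreas at the 1.43rd with 0.0393 and 0.0234. Over genes with 1 transcript these 4 lists no longer stood apart, at the 9.995th, 3.09th, 8.81st and 9.67th percentiles, as was the case for liver at the 19.3rd among genes at a mean of 1 FPKM or more and for neurons at the 3.89th in placenta 2 alone.

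Metabolic and stress-related lists differed widely in level. All 39 ribosomal protein genes reached 1 FPKM in both placentas, with medians of 489 and 502 FPKM at the 100th percentile, led by RPS18 at 1179 ± 37.1 (SD, n = 2). All 28 oxidative phosphorylation genes did so too, with medians of 45.3 and 45.7 FPKM at the 100th percentile, led by COX4I1 at 179 ± 21.4 (SD, n = 2). Immediate early and heat shock genes, which respond within minutes to handling and stress, reached the floor in 19 of 22 cases with medians of 13.0 and 21.4 FPKM at the 100th percentile, led by HSPB1 at 900.4 ± 79.6 and DUSP1 at 194 ± 43.6 (SD, n = 2 each). Hypoxia response genes did so in 19 of 21 cases, with medians of 9.24 and 13.95 FPKM at the 99.9th percentile, or the 90.4th among genes at a mean of 1 FPKM or more, and ADM, encoding the vasodilator adrenomedullin, had 718 ± 10.3 (SD, n = 2). Cell cycle genes did so in 21 of 24 cases, with medians of only 3.32 and 3.51 FPKM at the 94.1st percentile, or the 8.22nd among genes at a mean of 1 FPKM or more. PCNA was highest at 17.5 ± 1.63 FPKM, and the proliferation marker MKI67 had 0.548 ± 0.0461 (SD, n = 2 each).

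Immune-related lists followed. Genes of the major histocompatibility complex reached 1 FPKM in both placentas in 18 of 20 cases, with medians of 18.2 and 37.0 FPKM at the 100th percentile, led by B2M at 1297 ± 173, HLA-A at 259 ± 69.6 and HLA-E at 187 ± 10.1 (SD, n = 2 each). Reads of the HLA copies cannot be assigned with certainty. Complement genes and their regulators did so in 16 of 20 cases, with medians of 12.1 and 23.2 FPKM at the 100th percentile, or the 93.5th over genes with 1 transcript, led by SERPING1 at 117 ± 5.55 (SD, n = 2). Interferon-stimulated genes did so in 14 of 21 cases, with medians of 1.89 and 2.03 FPKM at the 72.9th percentile, or the 0.375th among genes at a mean of 1 FPKM or more, although IFI6 had 180 ± 28.9 and IFI27 had 177 ± 128 (SD, n = 2 each). Interferon lambda genes and interferon receptors did so in 6 of 10 cases, all of them receptor genes, with medians of 4.12 FPKM in each placenta at the 85.3rd percentile. IFNGR1 was highest at 44.7 ± 9.78 FPKM (SD, n = 2), while the lambda genes IL29, IL28A and IL28B and the beta gene IFNB1 were under 1 FPKM in both. In the list of X inactivation and Y-linked genes, 1 of 12 reached the floor, XIST (chromosome X, 73040495 to 73072588) at 48.2 ± 6.37 FPKM (SD, n = 2), and the list stood at the 1.91st percentile with medians of 0.0353 and 0.0578 FPKM, but at the 3.12th in placenta 2 alone and the 31.5th over genes with 1 transcript. XIST overlaps its antisense partner TSIX, and whether strand was used in the estimates is not given in the sources used here.

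Of the 33 lists, 17 stood in the upper 2.5% of random lists in level and 5 in the lower 2.5%, where chance alone would put 0.825 in each direction. The lists were picked for known cell types and functions, while random lists came from all usable genes, many of them under 1 FPKM. The comparison with chance is therefore no test. Among genes at a mean of 1 FPKM or more, 15 lists stood in the upper 2.5%.

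**Figure D1:**
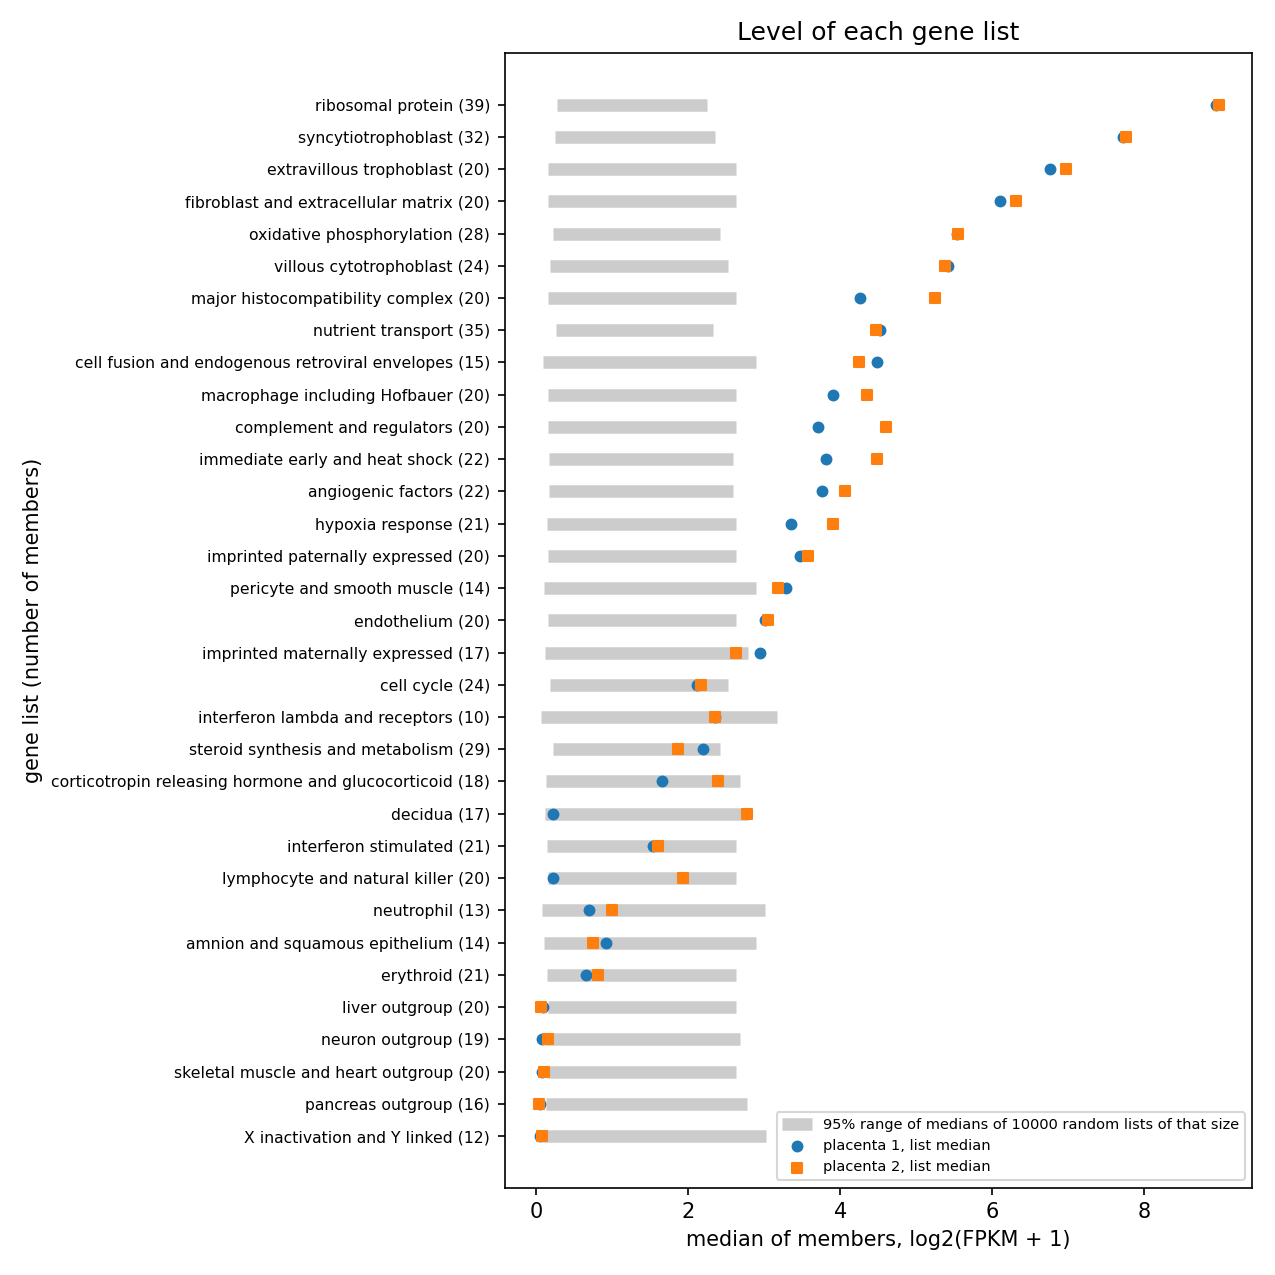
Median expression of each gene list in placenta 1 (circles) and placenta 2 (squares), as log2(FPKM + 1), with the number of members in parentheses; grey bars span the central 95% of medians of 10000 random lists of the same size. Ribosomal protein and syncytiotrophoblast lists lie far to the right of their bars in both placentas, at 489 and 209 FPKM in placenta 1, and the 4 outgroup tissues lie at the left ends.

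The placentas agreed closely for most genes. Across 25145 genes, which are not independent replicates, log2(FPKM + 1) had a Pearson correlation of 0.940 and a Spearman correlation of 0.951. Among the 7726 genes at a mean of 5 FPKM or more, the median absolute difference was 0.20 on the log2(FPKM + 1) scale, and 94.8% of genes lay within 2-fold. In that set 246 genes were at least 2-fold higher in placenta 2 and 158 at least 2-fold lower. Small RNA genes made up much of this count, since 189 of 327 differed at least 2-fold. Without them, 159 genes were higher and 56 lower among 7399, and 97.1% lay within 2-fold. This is 1 placenta against another, so these counts rest on size alone and the differences have no replicate check.

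IGFBP1, from the decidua list, and GZMA, GNLY and GZMB, from the lymphocyte list, were among the 12 genes with the highest differences in placenta 2. IGFBP1, secreted in large amounts by decidual cells, was 187-fold higher there, a log2 difference of 7.53. The protease gene KLK3 had 6.81 FPKM in placenta 1 and 715 in placenta 2, a log2 difference of 6.52, although reads of the kallikrein copies cannot be assigned with certainty. The killer cell granule genes GZMA, GNLY and GZMB differed by 6.22, 5.57 and 5.16. GZMA had 0.167 and 86.1 FPKM, GNLY 0.683 and 79.0, and GZMB 0.612 and 56.7. The other genes among the 12 with the highest differences were C2orf40 at 6.11, LOC100294406 in the immunoglobulin kappa region (chromosome 2, 89148206 to 89476123) at 5.98, the protease inhibitor gene SERPINA3 at 5.65, the chemokine gene CCL23 at 5.36, the matrix gene POSTN at 4.88, CRISP3 at 4.79 and the complement gene C3 at 4.72. With a pseudocount of 5 in place of 1 the differences were 4.14 for GZMA, 3.67 for SERPINA3, 2.72 for CRISP3 and 3.02 for C3, and with a pseudocount of 0.1 that of CRISP3 was 7.48.

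Differences in the opposite direction were smaller. The 12 genes lowest in placenta 2 ranged from LOC100506349 at -2.91 (chromosome 22, 39080356 to 39099041) to CRH at -1.60. Between them lay the mitochondrial sirtuin gene SIRT4 at -2.09, the sodium pump subunit gene ATP1B1 at -2.05, the adenosine receptor gene ADORA2B at -2.02, C1RL at -2.02, the alpha globin gene HBA1 at -1.98, OPLAH at -1.95, the pyroptosis gene GSDMD at -1.82, DCXR at -1.79, ART5 at -1.63 and C15orf52 at -1.61. With a pseudocount of 5, C1RL fell to -1.14 and C15orf52 to -0.99, no longer 2-fold. ATP1B1 had 78.2 FPKM in placenta 1 and 18.1 in placenta 2, and GSDMD had 153 and 42.6. HBA2, the near-identical copy of HBA1, differed the other way with 1.80 and 5.61 FPKM. HBA2 was named after its values were seen. CRH was 3.05-fold higher in placenta 1.

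**Figure D2:**
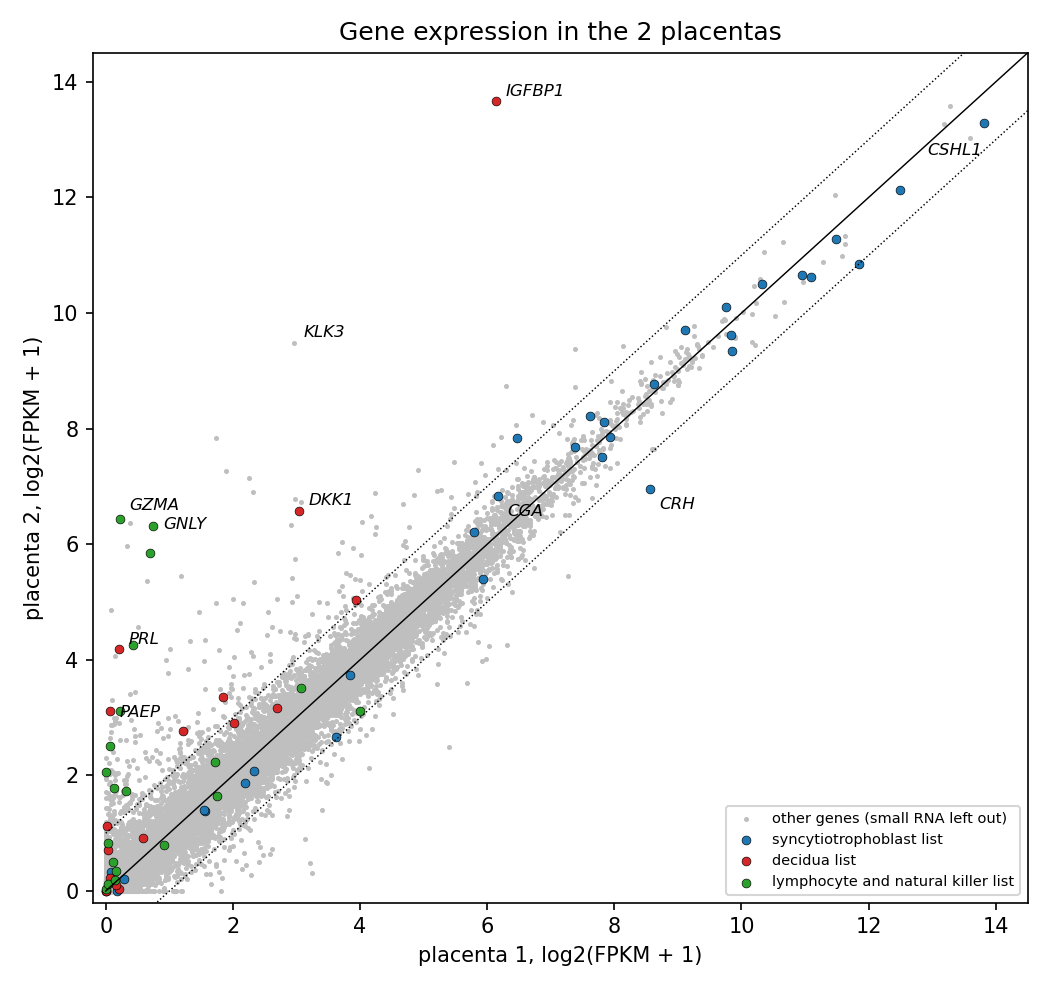
Expression of each gene in placenta 1 (horizontal) and placenta 2 (vertical), both as log2(FPKM + 1), with small RNA genes left out; the solid line marks equality and dotted lines a 2-fold difference. IGFBP1, KLK3, GZMA and GNLY lie far above the diagonal, CRH lies below it, and most of the syncytiotrophoblast list (blue) lies near it.

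Compared as lists, decidua, lymphocyte, histocompatibility and macrophage genes were higher in placenta 2, and the syncytiotrophoblast list, both imprinted lists and the pericyte and smooth muscle list were slightly lower. Among list members at a mean of 1 FPKM or more, all 9 of the 17 decidua genes kept by that filter were higher in placenta 2, 7 of them at least 2-fold, with a median log2 difference of 1.56 at the 100th percentile of 10000 random lists matched on expression. The decidua median was 0.91 with no filter, 0.94 with a pseudocount of 5 and 2.53 at a mean of 5 FPKM or more, past the limit each time. PRL, the prolactin gene, had 0.158 and 17.2 FPKM, PAEP, encoding glycodelin, 0.0505 and 7.66, DKK1, a Wnt inhibitor, 7.22 and 94.5, and HAND2 14.3 and 32.0. Lymphocyte and natural killer genes had a median difference of 2.06 at the 100th percentile, with 11 of 13 members higher and 9 at least 2-fold, out of 20 genes listed. That median was 0.66 with no filter, 0.71 with a pseudocount of 5, 4.87 with a pseudocount of 0.1 and 4.49 at a mean of 5 FPKM or more, so its size depends on the treatment of low values, while it passed the limit each time. NCAM1 was among the exceptions, with 14.9 FPKM in placenta 1 and 7.70 in placenta 2. The histocompatibility list had a median of 1.02 at the 100th percentile, with 18 of 20 members higher and 10 at least 2-fold, or 0.59 with a pseudocount of 5. On the log2(FPKM + 1) scale, HLA-DRA with 11.6 and 56.8 FPKM and CD74 with 27.9 and 115, both of class II antigen presentation, differed most. Of the class I genes, HLA-B had 70.6 and 157 FPKM, HLA-C 77.4 and 155 and HLA-E 194 and 179. These are values of the human genes, and macaque reads of the HLA copies cannot be assigned to them with certainty. The macrophage list had a median of 0.51 at the 100th percentile, with 18 of 19 members higher, among them SPP1 with 18.1 and 77.4 FPKM. PRL, PAEP, NCAM1, HLA-DRA, CD74, HLA-B and HLA-C were named after their values were seen, as were PCSK1, MMP12 and EFEMP1 among the lists that follow.

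The other lists in the upper 2.5% of random lists were higher in placenta 2 too, beside the decidual and lymphocyte differences. Immediate early and heat shock genes had a median of 0.48 at the 100th percentile, with FOS, JUN, ZFP36, FOSB and EGR1 at least 2-fold higher, and these 5 were named after their values were seen. EGR1 had 3.31 and 24.0 FPKM. Hypoxia response genes had a median of 0.34 at the 99.96th percentile, nutrient transport genes 0.25 at the 99.94th (0.16 with a pseudocount of 5), angiogenic factors 0.22 at the 98.8th and complement genes 0.22 at the 98.6th (0.37 at a mean of 5 FPKM or more). Over genes at a mean of 5 FPKM or more, the angiogenic list had a median of 0.19 and no longer passed the limit. Neutrophil genes had a median of 0.53 at the 99.9th percentile over 6 members, or 0.35 with a pseudocount of 5 and 0.81 at a mean of 5 FPKM or more, and erythroid genes 0.53 at the 99.9th over 9, or 0.27 with no filter. The liver list had a median of 1.12 at the 99.9th percentile and the pancreas list 1.63 at the 99.9th, each over only 3 members, or 0.57 and 0.55 with a pseudocount of 5. Without the expression filter the neutrophil median was 0.02 and those of liver and pancreas were 0, within their random ranges.

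Lists in the lower 2.5% of random lists were lower in placenta 2. The syncytiotrophoblast list had a median of -0.20 at the 0.08th percentile (-0.11 with a pseudocount of 5), with 10 of 28 members higher, CRH and CSH1 at least 2-fold lower and PSG1 at least 2-fold higher. CSH1 had 3679 and 1837 FPKM. Maternally expressed imprinted genes had a median of -0.32 at the 0.19th percentile, with 2 of 11 members higher, and paternally expressed ones -0.23 at the 0.41st, with 7 of 16 higher. These medians were -0.20 and -0.19 with a pseudocount of 5, -0.22 and -0.20 with no filter and -0.33 and -0.38 at a mean of 5 FPKM or more, past the limit each time. Pericyte and smooth muscle genes had -0.19 at the 1.97th percentile, with 4 of 13 higher, and -0.15 within the random range without the expression filter or at a mean of 5 FPKM or more.

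The remaining 13 lists that could be compared lay between the limits. Fusion genes had a median log2 difference of 0.16 at the 91.3rd percentile, interferon receptors and lambda genes 0.20 at the 91.2nd (0.09 with no filter), fibroblast and matrix genes 0.12 at the 83.9th, interferon-stimulated genes 0.06 at the 70.9th (0.28 at a mean of 5 FPKM or more) and cell cycle genes 0.04 at the 64.8th. Endothelial genes had 0.05 at the 57.2nd, oxidative phosphorylation genes 0.05 at the 55.6th, and amnion and squamous genes 0.02 at the 52.4th. Genes of corticotropin-releasing hormone and glucocorticoids had 0.03 at the 49.1st percentile, with CRH at least 2-fold lower and PCSK1 at least 2-fold higher. PCSK1 was listed at 0 in placenta 1 and had 3.12 FPKM in placenta 2. Steroid synthesis genes had -0.02 at the 33.9th percentile and ribosomal protein genes 0.03 at the 24.2nd. Extravillous trophoblast genes had -0.02 at the 22.5th, with 1 member at least 2-fold lower, MMP12, at 8.48 and 0.240 FPKM. Villous cytotrophoblast genes had -0.06 at the 13.4th, with 2 members at least 2-fold higher, among them the matrix gene EFEMP1 with 58.8 and 169 FPKM. Medians this near 0 have no firm size or sign. With equal sums they were 0.10 for endothelial and oxidative phosphorylation genes, 0.08 for cell cycle genes and -0.01 for villous cytotrophoblast genes, and those of the amnion, corticotropin-releasing hormone, steroid, ribosomal protein and extravillous lists changed sign under another scaling or filter. Of 30 lists compared, 13 lay in the upper 2.5% of random lists and 4 in the lower 2.5%, where chance would put 0.75 in each direction if lists and genes were independent. Some lists share members, and members of a list can vary together, so these counts do not give a number of separate differences. The muscle and heart, neuron and X-inactivation lists had too few members at a mean of 1 FPKM for this comparison.

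**Figure D3:**
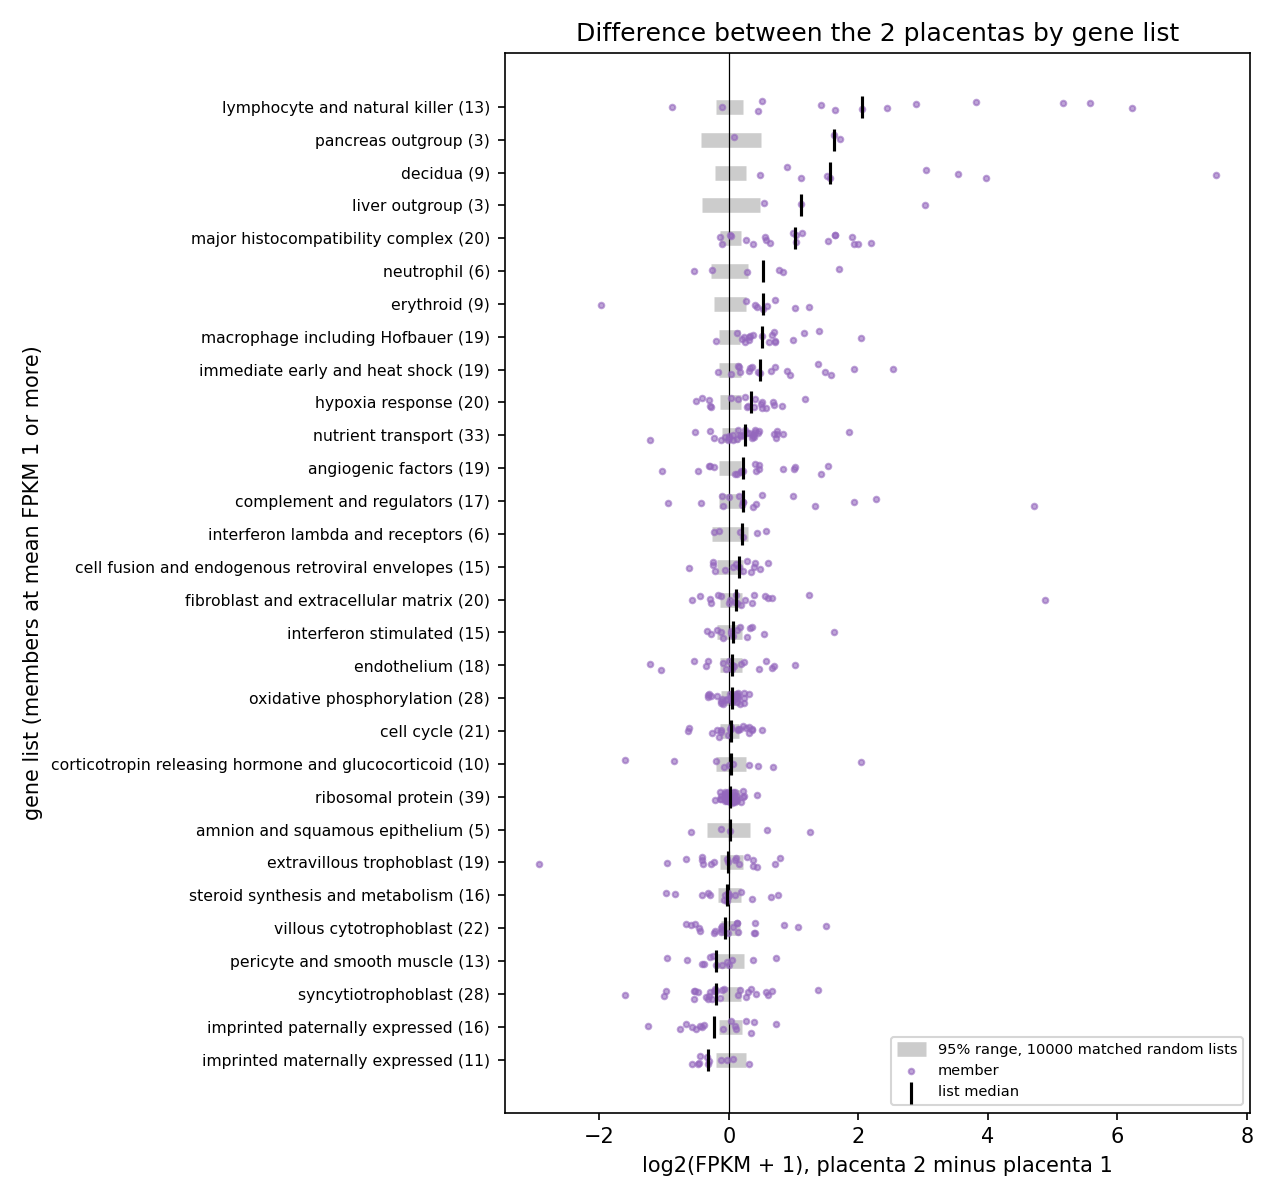
Difference between the placentas for each gene list, as log2(FPKM + 1) in placenta 2 minus placenta 1; points are members at a mean of 1 FPKM or more, black ticks list medians and grey bars the central 95% of medians of 10000 random lists matched on expression. The lymphocyte and natural killer median of 2.06 and the decidua median of 1.56 lie far to the right of their bars, while ribosomal protein genes cluster around 0.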

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

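Leaving out small RNA genes or genes with several transcripts was chosen as an alternative after the data were seen, as was comparing the added lists with no filter. No paired analysis was possible because the labels give 1 group. Alternatives based on confidence intervals, for genes detected and for 2-fold differences, were not run because the files hold none, and results between the placentas cannot leave out a placenta. With 1 placenta left out, genes detected ranged from 12742 to 12771, 23 of the 25 most abundant genes were shared in either case, the top 10 share ranged from 19.1% to 19.4%, the top 100 share from 38.5% to 39.2%, and lists high in level from 17 to 18. At a floor of 5 FPKM, 7134 genes were detected. With small RNA genes kept, 6 of the 25 most abundant genes were shared, and the top 10 and top 100 shares were 20.9% and 57.7%, since short genes take large FPKM. Over genes at a mean of 1 FPKM or more the Pearson and Spearman correlations were 0.863 and 0.902, and at 5 FPKM or more 0.756 and 0.845. Low genes shared by both placentas drop out of these sets, while small RNA genes, which often differed, were not left out. Which of these lowered the correlations was not tested. Genes at least 2-fold higher in placenta 2 numbered 406 at a mean of 1 FPKM or more, 441 with no filter and 162 at 20 FPKM or more. Without small RNA genes 159 were higher and 56 lower. Rescaling multiplied placenta 2 by 1.03 for equal sums and by 0.981 for the median ratio, and left all these counts within 1.5 times. The counts of lists kept within 1.5 times under every alternative run, 14 to 18 high in level, 10 to 13 higher and 3 to 4 lower in placenta 2. Among list levels, list differences and named genes' differences under these alternatives, 452 values kept their direction and side of the limit, 7 passed a limit they had missed, 23 no longer passed one and 19 turned. All 19 were short of a limit in the main setting. Levels turned at a mean of 1 FPKM or more for lymphocyte (2.48th percentile), decidua (28.8th), erythroid (97.4th), amnion (92.6th), cell cycle (8.22nd) and interferon-stimulated genes (0.375th), of which the first and last then stood in the lower 2.5%. They also turned with a pseudocount of 0.1 for lymphocyte (39.5th) and decidua genes (47.0th), over genes with 1 transcript for erythroid genes (56.7th), and with 1 placenta left out, when the lymphocyte level ranged from 5.98 to 85.5 and the decidua level from 7.53 to 97.4. Differences turned with equal sums for extravillous (0.030) and steroid genes (0.027), with the median ratio for amnion (-0.011) and ribosomal protein genes (-0.0030), with no filter for extravillous (0.016) and amnion genes (-0.049), and at a mean of 5 FPKM or more for genes of corticotropin-releasing hormone (-0.036) and the amnion (-0.051). Depth is unknown, so values under 1 FPKM cannot be given an error.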

Other observations

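In this part, the tests of blood, library scaling and syncytiotrophoblast share were chosen only after the result was seen, while the added decidual stroma and natural killer lists and the test of conserved genes were written before. The genes in this paragraph were chosen after their values were seen. IGFBP1 was not the only binding protein of insulin-like growth factors to differ: IGFBP6 had 3.97 FPKM in placenta 1 and 119 in placenta 2, IGFBP2 had 77.8 and 426, IGFBP4 36.1 and 120 and IGFBP7 37.8 and 122. IGFBP3, abundant in both, had 610.3 and 777 FPKM, and IGFBP5 had 10.8 and 8.17.

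Transcript estimates divided some genes unevenly, as Cufflinks assigned them. The full-length transcript of FLT1, which encodes the membrane receptor, held 6.03% of the gene's FPKM in placenta 1 and 6.19% in placenta 2, and the shorter ones, which encode soluble forms, held 94.0% and 93.8%. For aromatase, the CYP19A1 transcript that reaches the far upstream end of the locus (chromosome 15, 51500254 to 51630795) held 37.2% and 32.4%. A cluster of 46 microRNA precursors on chromosome 19 (54169927 to 54265684), with a median length of 87 bases, was above 0 for 12 precursors in placenta 1 and 11 in placenta 2, and for 7 in both. Short precursors are poorly captured by this kind of library, so these are listed as values.

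Decidual and cytotoxic lymphocyte genes were higher in placenta 2, and a candidate explanation is more decidua, the maternal tissue that adjoins the villi, in that biopsy. A natural killer list not looked at before had a median log2 difference of 1.499 at the 100th percentile, with 8 of 9 members higher, and over all 21 of its genes, a test added after the data were seen, 0.49 at the 100th percentile with 19 higher. These genes mark the same killer cells as the granule genes that had already been seen to differ, so they extend the pattern. They cannot tell decidua from blood or another source of such cells. A decidual stroma list had 0.16 at the 92.3rd percentile over 16 of 20 genes, with 10 higher, 4 at least 2-fold higher and 0 at least 2-fold lower, or the 97.6th over all 20, under the bound of 0.3 set in advance by less than the spread of random lists (-0.15 to 0.21), so it does not decide. Scaling is argued against by its small size, since the rescalings shifted placenta 2 by only 0.049 or -0.028 on the log2 scale. The lower of the decidua and lymphocyte medians was 1.54 afterwards, which such small shifts made certain to stay near its value before. More blood was compared with the pooled genes. There, 15 neutrophil and erythroid genes had a median of 0.53 (quartiles 0.27 and 0.81), and 22 decidua and lymphocyte genes had 1.85 (0.96 and 3.75). With a pseudocount of 5 or no filter these quartiles overlapped, so the pooled comparison does not decide. All 9 decidua genes kept by the filter, picked as markers of decidua, were higher, with a median of 1.56 (random range -0.21 to 0.27). This argues against more blood alone for the decidua genes, and blood stays open for the lymphocyte genes. Other biopsy content and a difference between the animals stay open and untested, and the labels do not describe the biopsies.

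CRH was 3.05-fold higher in placenta 1. A smaller share of syncytiotrophoblast in placenta 2 is argued against, since the other 27 syncytiotrophoblast markers had a median log2 difference of -0.19 with quartiles of -0.34 and 0.28, none as low as CRH at -1.60. Scaling is argued against too, since the rescaling shifts of 0.049 or -0.028 were far smaller than the CRH difference, which stayed at -1.55 or lower. A difference of a few days of gestation or between the animals stays open and untested, as does any effect of the assignment of reads to human sequence.

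The ratio of coverage to FPKM is a property of the estimates and not of expression, yet it varied by gene. It ranged from 1.33 to 2.66 in placenta 1 and from 1.28 to 2.56 in placenta 2, a span of 2.00-fold in each, and agreed across 11908 genes with a Pearson correlation of 0.974. On a scale from 0 at the lowest to 1 at the highest ratio, the median was 0.461, ribosomal protein genes had 0.680, syncytiotrophoblast genes 0.198, histocompatibility genes 0.185 and the growth hormone, lactogen and PSG families 0.0106. A candidate explanation is that in part of the fragments only 1 mate was placed on the human genome, less often in conserved genes. Ribosomal protein genes stood at the 100th percentile of length-matched lists but oxidative phosphorylation genes only at the 79.3rd, between the bounds set in advance, so the test does not decide. A dependence on multi-copy reads stays open and was not tested.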
